A study of Mus musculus with 6 samples.

How the data were processed

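Chronic lymphocytic leukaemia (CLL) cells were sorted from the spleens of mice that had received Eµ-TCL1 leukaemia cells by adoptive transfer. Eµ-TCL1 mice express the TCL1 oncogene in B cells and develop a CD5-positive B-cell leukaemia. Recipients were given PF-670462, an inhibitor of casein kinase 1 delta and epsilon, or its vehicle. Per the labels' protocols, 3' end libraries with unique molecular identifiers (UMIs) were made with a QuantSeq forward kit. All 6 libraries carry the same batch label, so no batch could be separated from the groups or tested.

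The deposited table holds whole-number counts per gene for 6 libraries, which the authors made from their reads. It has 54232 genes, 0 rows that name no gene and 0 columns of no sample. The submitters' processing notes list bcl2fastq 2.20.0.422, UMI-tools 1.1.1, FastQC 0.11.9, Trimmomatic 0.36, STAR 2.7.3a, Picard 2.18.27, featureCounts 1.6.3, limma and Seurat, with the genome build GRCm38.p6, and give no role or order for them. Whether UMIs were collapsed before counting, and which strand setting was used, is not given in the sources used here. If UMIs were not collapsed, counts are not independent molecules. Intervals and floors therefore cover counting error only. Library totals ran from 2472064 to 3105137 counts, so 1 count was worth 0.322 to 0.405 CPM, the count scaled to a common library size. Over the 6 libraries together, a gene with a count of 0 can have a level of up to 0.176 CPM, the value of 3 counts.

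Gene identifiers were matched to the GENCODE M21 annotation of GRCm38, the same build, for coordinates and gene types. Of the identifiers, 54165 matched and 67 did not. The symbols are those of the table, or of GENCODE for the 22496 genes without a symbol there. Reads shared by near-identical copies can be lost or split in counting, so ribosomal protein genes are uncertain. The mitochondrial genes COX2, COX3, ATP6 and ATP8 had 0 or 1 count in every library, although cells use them, and 7 of the 13 protein genes of the mitochondrial list could be tested.

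Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (a minimum count of 10, scaled to library size, and a minimum total of 15), which left 10067 genes. Libraries were scaled by TMM, and CK1i was compared with CTRL by the robust quasi-likelihood F test in its current, bias-adjusted form. Benjamini-Hochberg adjustment covered all tested genes, and adjusted p under 0.05 was the threshold. The standard error (SE) of a log2 fold change is its size divided by the root of the F statistic. CPM values of single genes are scaled by TMM, and log2 CPM uses a prior count of 2. All tests were two-sided.

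Before the data were examined, 40 gene lists were fixed: casein kinase 1 family, circadian clock, canonical Wnt targets, noncanonical Wnt and planar cell polarity, B-cell receptor signalling, B-cell activation response, immediate early and dissociation, chemokines and their receptors, adhesion and egress, actin and migration, proliferation, MYC targets, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, proteasome, histones, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and integrated stress response, heat shock, p53 targets, BCL2 family, type I interferon response, interferon gamma and antigen presentation class I, MHC class II, immune regulatory ligands and cytokines, B-1 and CLL phenotype, follicular and marginal zone B cells, germinal centre B cells, plasma cells, T cells, NK and cytotoxic cells, monocytes and macrophages, neutrophils, dendritic cells, erythroid cells, platelets and megakaryocytes, spleen stroma and endothelium, and sex-linked genes. Of all members, Ahsp alone was not found. The 32 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A list score is the mean log2 CPM of the tested members in a library. Scores and shares of counts were compared by an exact permutation test over the 20 assignments of 6 libraries, which cannot give a p below 0.1.

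The genes named in the text follow a rule with 3 parts, also fixed beforehand. The first part took the largest changes among genes past the threshold with groups that did not overlap and a mean of at least 5 CPM, without immunoglobulin variable segments, pseudogenes and Gm or Rik models. With fewer than 10 genes past the threshold it took the 10 with the smallest p in each direction, which is what applied. The second part took up to 4 members of each list past the threshold, or, where none passed, up to 2 with the smallest p. The third part always included Csnk1d, Csnk1e, Csnk1a1, Per1, Per2, Axin2, Lef1, Ror1, Cd5, Mki67, Cxcr4, Ccl3 and Ccl4, where tested. Some genes that the rule takes are not reported here. Any other named gene was chosen after its values were seen.

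The procedure was tested on simulated counts drawn from the means and library sizes of the CK1i and CTRL libraries, 10067 genes with 200 changed in each of 5 data sets. It recovered 20.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 93.0% of those changed 3-fold, and called a median of 9 unchanged genes per data set. Simulated lists of 34 genes raised 1.5-fold were found in 20 of 20 data sets, and unchanged lists in 1 of 20. The simulated genes varied independently of each other, which real genes do not. With 200 changed genes present, the adjusted threshold was also easier to reach than with few changed genes. The recovered shares may therefore be too high for the real data, where Traf3 did not pass at a log2 fold change of 2.87.

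Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, library sizes without immunoglobulin, mitochondrial and haemoglobin genes, no filter, a filter of 10 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, the legacy quasi-likelihood form, an adjusted p under 0.1, a minimum fold of 1.2, and leaving out each library in turn. Lists were also tested on limma-voom values, and shares without immunoglobulin counts. Added after seeing the data were the unadjusted count, separate S phase and G2 and M phase lists, removal of trends on transcript GC content, length and mean expression (loess, span 0.4), the immediate early score as a covariate, thinning of all libraries to the smallest total, and the estimated correlation for the split of the libraries with the most called genes.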

Results

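Gene expression was measured in splenic CLL cells from the Eµ-TCL1 transfer model after treatment of the recipients with PF-670462 (CK1i, 3 libraries) or vehicle (CTRL, 3 libraries). The inhibitor was given by mouth at 50 mg/kg in 10% kolliphor in PBS, in cycles of 5 days on and 2 days off, from day 5 after cell transfer, and treatment lasted 8 weeks in all. The CK1i libraries held 3105137, 3045311 and 2472064 counts for replicates 1, 2 and 3, and the CTRL libraries 2859649, 2472320 and 3064371. Between 14339 and 14836 genes had a count in a library. The labels do not state that each library came from its own mouse, so p-values measure the spread between these samples, which could be technical. Pairwise correlations of log2 CPM across genes, which are not independent replicates, were 0.962 to 0.974 within groups and 0.961 to 0.976 between groups. Chi-square per degree of freedom between libraries, which is near 1 for sampling noise alone, was 6.59 to 11.2 within groups and 4.22 to 11.7 between groups, so no pair of libraries had counts that agreed within sampling noise. The first principal component took 28% of the variance and did not separate the groups (exact permutation p = 0.3). It set CTRL replicate 1, at 31.4, apart from the other 5 libraries, which lay between -12.4 and 4.68.

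The comparison of CK1i with CTRL asks how leukaemia cells that grew under casein kinase 1 inhibition differ in expression. In genes of the cell division cycle, all 34 tested members of the proliferation list had higher values in CK1i libraries, with a median log2 fold change of 0.62. Ube2c, which encodes a ubiquitin-conjugating enzyme of the anaphase-promoting complex, had 50.5 ± 17.1 CPM in CK1i and 18.7 ± 6.54 CPM in CTRL (SD, n = 3). Ccnb2, a mitotic cyclin, had 42.7 ± 4.17 and 21.93 ± 6.997 CPM, and Mki67, the gene of the Ki-67 proliferation marker, 223 ± 72.0 and 115 ± 40.1 CPM. No single gene passed the threshold over all tested genes.

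The proliferation list was called higher by camera with the preset correlation (adjusted p = 3.0e-37), and was not called with an estimated correlation (p = 0.034, adjusted p = 0.56), the members having an estimated inter-gene correlation of 0.66. Of its members, 20 had an unadjusted edgeR p under 0.05, all higher, and 15 passed when adjusted over the list alone. In 20 of the 34 genes all 3 CK1i libraries lay above all 3 CTRL libraries, where chance gives 5% of genes this order and 10% a difference without overlap in either direction. The list scores were 6.29, 6.69 and 6.29 in CK1i replicates 1 to 3 and 5.28, 6.13 and 5.86 in CTRL replicates 1 to 3, so the groups did not overlap (exact permutation p = 0.1, the smallest possible; adjusted p = 0.76 over the lists). CTRL replicate 1 had the lowest score and is the library apart on the first component; without it the median log2 fold change was 0.40. The list also holds genes of DNA replication. Those of the MCM helicase had log2 fold changes of 0.079 ± 0.23 for Mcm2, 0.40 ± 0.27 for Mcm3, 0.59 ± 0.22 for Mcm4, 0.37 ± 0.25 for Mcm5, 0.38 ± 0.15 for Mcm6 and 0.32 ± 0.22 for Mcm7 (SE), all named after their values were seen.

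**Figure D1:**
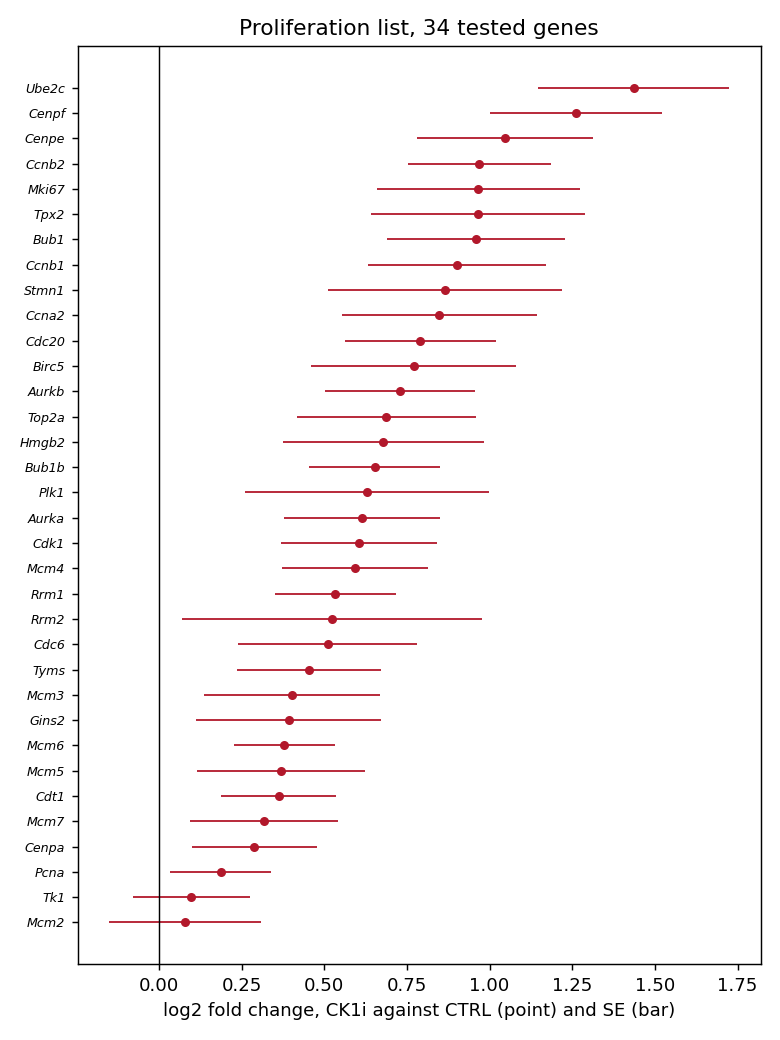
Log2 fold change of CK1i against CTRL (x axis; points, with bars of 1 SE) for the 34 tested genes of the proliferation list (y axis), 3 libraries per group. All 34 points lie above 0, from 0.079 for Mcm2 to 1.44 for Ube2c.

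Over all 10067 tested genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower, with a smallest adjusted p of 0.224. At an unadjusted p under 0.05 there were 272 higher and 201 lower genes, 473 in all, against 503 expected by chance. limma-voom also called 0, while DESeq2 called 6 higher and 2 lower. All CK1i libraries lay above all CTRL libraries for 525 genes and below them for 451, which is 9.70% of genes where chance gives 10%. The biological coefficient of variation was 0.16 and the median SE of a log2 fold change 0.195.

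The 10 higher genes with the smallest p were Troap, Traf3, Kntc1, Kif20a, Lmo7, Sgo2a, Ube2c, Nusap1, Brca2 and Ccnb2. Kif20a is a kinesin of cytokinesis, Nusap1 a spindle protein, Kntc1 a kinetochore protein and Sgo2a a shugoshin that guards centromeric cohesion. Troap (ENSMUSG00000032783), at chromosome 15, 99074575 to 99083409 on GRCm38, had 29.4 ± 5.85 CPM in CK1i and 10.95 ± 2.25 CPM in CTRL (SD, n = 3), a log2 fold change of 1.43 ± 0.24 (SE; edgeR adjusted p = 0.224). It passed the threshold in DESeq2 (adjusted p = 0.0060) and in edgeR with no filter (adjusted p = 0.0020). Lmo7 also passed in both (0.046 and 0.018), and Ube2c, Nusap1 and Cenpf, the last named after its values were seen, passed in DESeq2 (0.0060, 0.020 and 0.0060). Traf3, which encodes an adaptor that restrains noncanonical NF-kB signalling in B cells, had the largest log2 fold change of the 20 leading genes, 2.87 ± 0.46 (edgeR adjusted p = 0.224). It lies at chromosome 12, 111166370 to 111267153. Its counts were 68, 31 and 87 in CK1i replicates 1 to 3 and 7, 8 and 10 in CTRL replicates 1 to 3. Traf3 passed the threshold in DESeq2 (adjusted p = 1.5e-05) and in edgeR without CK1i replicate 2 (log2 fold change 3.22, adjusted p = 0.0022).

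The 10 lower genes with the smallest p were Wnt10a, Gm23935, Gm37529, Slc1a4, C130051F05Rik, Bcl2l11, Atf5, Fpgs, Smyd5 and Rarg. Gm23935 passed in DESeq2 (adjusted p = 0.020). Wnt10a (ENSMUSG00000026167), a secreted Wnt ligand at chromosome 1, 74791516 to 74804179, had 19.7 ± 1.99 CPM in CK1i and 48.2 ± 14.8 CPM in CTRL (SD, n = 3), a log2 fold change of -1.29 ± 0.23 (SE; edgeR adjusted p = 0.224). It passed in DESeq2 (adjusted p = 0.0060), in edgeR with no filter (adjusted p = 0.0020) and in edgeR without CTRL replicate 3 (log2 fold change -1.51, adjusted p = 0.025). Bcl2l11, which encodes the pro-apoptotic protein BIM, had a log2 fold change of -0.71 ± 0.20, and Slc1a4, a neutral amino acid transporter, -1.03 ± 0.26. Of the 20 leading genes, 12 overlap another annotated gene. For Troap, Traf3, Ube2c, Brca2 and Fpgs each overlapping gene held 0 to 3 counts over the 6 libraries. Counts are uncertain for Kif20a, Sgo2a, Nusap1 and Atf5, whose tested partners held 110 to 2411 counts, and for C130051F05Rik, whose partner Fam172a held 1390. They are most uncertain for Gm23935 and Gm37529, whose partners Zc3h7a and Rabgap1l held 3906 and 5065.

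**Figure D2:**
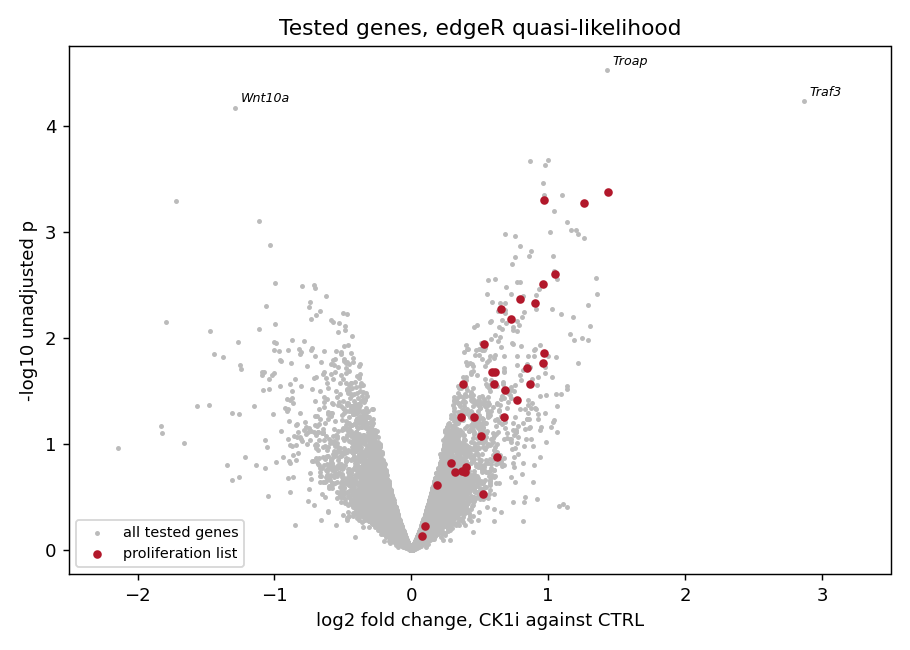
Log2 fold change of CK1i against CTRL (x axis) and -log10 of the unadjusted edgeR p (y axis) for the 10067 tested genes, with the proliferation list in red. The 34 list genes all lie to the right of 0, and Troap, Traf3 and Wnt10a have the smallest p.

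Most clock genes had lower values in CK1i libraries. Of the 14 tested members of the circadian clock list 12 were lower, with a median log2 fold change of -0.36. The core clock genes Arntl and Nr1d2 were not, with 0.045 ± 0.16 and 0.14 ± 0.24 (SE), both named after their values were seen. Per2, a repressor of the clock, had 7.83 ± 0.63 CPM in CK1i and 11.8 ± 3.04 CPM in CTRL (SD, n = 3), and Tef, a clock-controlled transcription factor, 36.3 ± 6.10 and 52.99 ± 11.1 CPM. Per1 varied widely within the groups, from 30.99 to 117 CPM in CK1i and from 45.1 to 119 CPM in CTRL. The list was called lower by camera (adjusted p = 0.0025) and was not called with an estimated correlation (p = 0.035, adjusted p = 0.56). None of its members passed when adjusted over the list alone, and without CK1i replicate 2 the list was not called (median -0.28, camera adjusted p = 0.0708). The scores of all 3 CK1i libraries lay below those of all 3 CTRL libraries (4.39 ± 0.19 and 4.70 ± 0.14, SD, n = 3; exact permutation p = 0.1).

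The kinases themselves showed no difference past the threshold. Csnk1d, which encodes casein kinase 1 delta, had a log2 fold change of -0.17 ± 0.14 (SE), Csnk1e, which encodes the epsilon form, -0.30 ± 0.19, and Csnk1a1 0.01 ± 0.14. The casein kinase 1 family list was not called (6 tested, camera adjusted p = 0.60).

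All 15 members of the heat shock list had higher values in CK1i libraries, with a median log2 fold change of 0.43. Hsp90aa1, an inducible HSP90 chaperone, had 465 ± 102 CPM in CK1i and 321 ± 59.2 CPM in CTRL (SD, n = 3), and Hspd1, the mitochondrial HSP60, 198 ± 39.0 and 153 ± 5.02 CPM. Hspa1a, named after its values were seen, ranged from 530 to 2635 CPM within CK1i and from 93.4 to 1508 CPM within CTRL. The list was called higher by camera (adjusted p = 5.2e-06) and was not called with an estimated correlation (p = 0.17, adjusted p = 0.69), and 0 members passed adjusted over the list alone. List scores overlapped between the groups (exact permutation p = 0.4). The call was lost without CK1i replicate 1 (median 0.084, camera adjusted p = 0.096) and without CTRL replicate 2 (median 0.21, camera adjusted p = 0.107), and without CTRL replicate 1 the median was 0.67.

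Genes of interferon gamma response and class I antigen presentation were higher for 20 of 27 tested members, with a median log2 fold change of 0.12. H2-T22, a nonclassical class I gene, had 45.4 ± 2.01 CPM in CK1i and 28.3 ± 2.93 CPM in CTRL (SD, n = 3) and was the 1 member that passed adjusted over the list alone (edgeR adjusted p = 0.028). Gbp3, an interferon-induced GTPase, had 61.2 ± 2.40 and 44.5 ± 3.23 CPM. The list was called higher by camera (adjusted p = 0.0061) and was not called with an estimated correlation (p = 0.086, adjusted p = 0.68). Without CK1i replicate 3 the median was 0.026 and the list was not called (camera adjusted p = 0.219), and without CTRL replicate 1 the median was 0.20.

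MYC target genes were lower for 24 of 29 tested members, with a median log2 fold change of -0.13. The nucleolar genes Nop56 and Rrp9 had log2 fold changes of -0.48 ± 0.16 and -0.51 ± 0.20 (SE), and 0 members passed adjusted over the list alone. Myc itself had 0.28 ± 0.19. The list was called lower by camera (adjusted p = 0.023) and was not called with an estimated correlation (p = 0.21, adjusted p = 0.72). It was not called without CK1i replicate 2 (median -0.16, camera adjusted p = 0.0708) or without CTRL replicate 3 (median -0.060, camera adjusted p = 0.487), and without CTRL replicate 1 the median was -0.25.

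**Figure D3:**
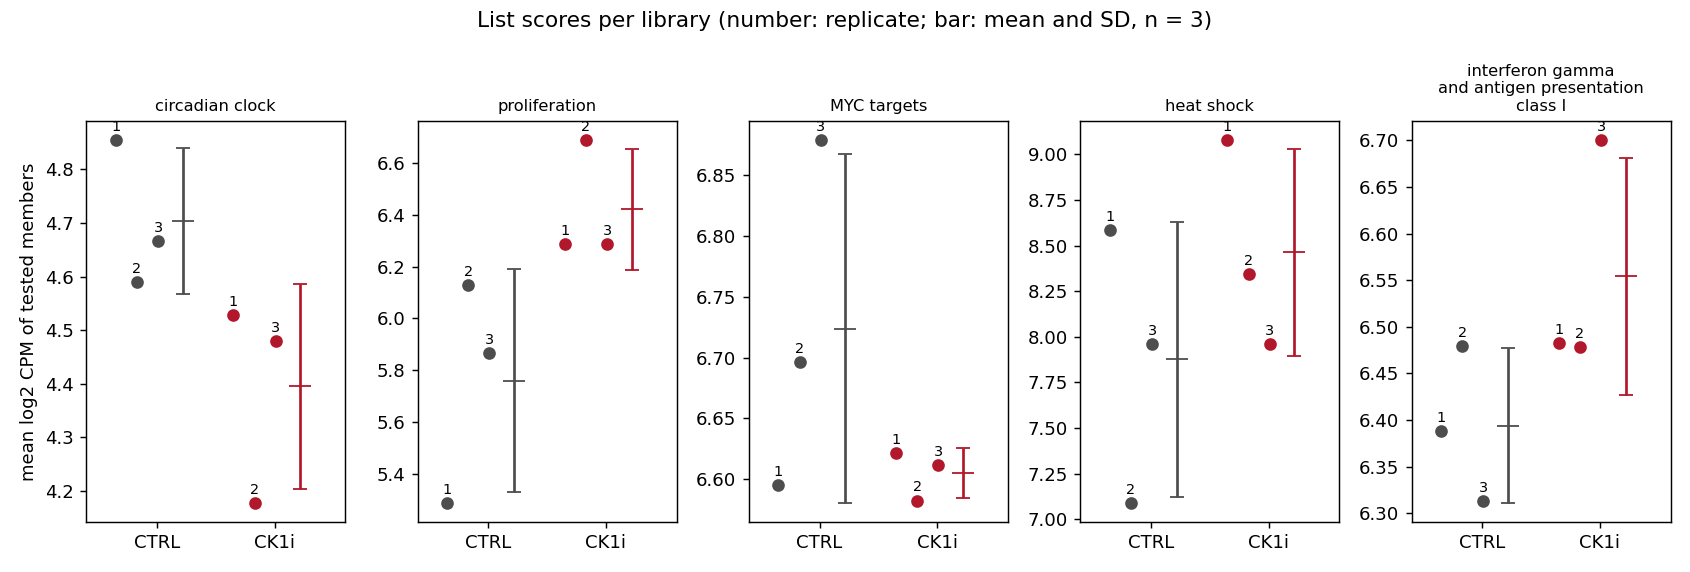
List score, the mean log2 CPM of a list's tested genes (y axis, a different range in each panel), for the 3 CTRL and 3 CK1i libraries of the 5 lists called by camera; numbers give the replicate and bars the mean and SD (n = 3). The groups are apart for the circadian clock and proliferation lists and overlap for the other 3.

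Wnt signalling genes gave no list call. Canonical Wnt targets had 5 tested members, 4 of them higher (camera adjusted p = 0.099), led by Tcf7 with a log2 fold change of 0.67 ± 0.26 (SE). Tcf7 is also a member of the T-cell list, so its value cannot be assigned to Wnt signalling alone. The median of the canonical Wnt list was 0.28. That list was called higher without CK1i replicate 2 (median 0.32) and without CTRL replicate 1 (0.50), and its median was 0.13 without CK1i replicate 1 and 0.080 without CTRL replicate 3. The noncanonical Wnt list had 7 tested members (camera adjusted p = 0.31); the Dishevelled genes Dvl1 and Dvl2 had -0.38 ± 0.15 and -0.48 ± 0.18, neither past the threshold. The median of this list was -0.026 and its mean 0.0092. Ror1, Wnt5a and Fzd6 had 0 counts in all 6 libraries, which allows up to 0.176 CPM each. Axin2, a target of canonical Wnt signalling, had 16 counts in all, 14 of them in CK1i replicate 3, and Lef1 had 15. Both were too low to test, as were Ccl3 with 3 counts and Ccl4 with 2.

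Genes of B-cell identity and signalling showed no list call. Cd5, a marker of this leukaemia, had 29.6 ± 1.99 CPM in CK1i and 29.8 ± 4.25 CPM in CTRL (SD, n = 3). The B-cell receptor signalling list had 17 of 29 members higher (camera adjusted p = 0.92), the B-cell activation list 16 of 24 lower (0.12) and the B-1 and CLL phenotype list 13 of 20 lower (0.18). The follicular and marginal zone B cells list had 10 of 14 members higher and came close to the threshold (camera adjusted p = 0.052, and 0.0479 with the stricter filter), led by Cd1d1 with a log2 fold change of 0.52 ± 0.19 (SE). With an estimated correlation its p was 0.056 and its adjusted p 0.59, and its scores were higher in all 3 CK1i libraries than in all 3 CTRL libraries (exact permutation p = 0.1). MHC class II genes (camera adjusted p = 0.69), germinal centre genes (0.50) and plasma cell genes (0.35; median 0.024, mean -0.11, tested as lower) were not called. With 1 library left out, 4 of these lists gained a call: B-cell activation without CK1i replicate 1 (median -0.38) and CTRL replicate 2 (-0.24), B-1 and CLL phenotype without CK1i replicate 1 (-0.15) and CTRL replicate 2 (-0.16), follicular and marginal zone without CK1i replicate 3 (0.18) and CTRL replicate 3 (0.36), and plasma cells without CK1i replicate 3 (-0.31) and CTRL replicate 3 (-0.17). The B-cell activation median turned to 0.077 without CK1i replicate 2 and also without CTRL replicate 1, and the plasma cell median was 0.18 and 0.12 without these libraries. The follicular and marginal zone median was 0.088 without CK1i replicate 2. Bcl6, a germinal centre regulator, had 5.65 ± 1.67 CPM in CK1i and 2.32 ± 0.86 CPM in CTRL.

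Genes of migration, chemokines and immune regulation were not called either. Cxcr4, the receptor of the homing chemokine CXCL12, had a log2 fold change of 0.08 ± 0.20 (SE). Icam2, an adhesion molecule, had -0.46 ± 0.16, not past the threshold. Camera adjusted p was 0.34 for chemokines and their receptors, 0.81 for adhesion and egress, 0.76 for actin and migration, and 0.18 for immune regulatory ligands and cytokines, whose scores were lower in all 3 CK1i libraries (exact permutation p = 0.1). Of the 40 fixed lists, the neutrophil and platelet lists had no tested gene and so no score. Among the others, the scores of 5 were apart between the groups, where chance gives 10% without overlap. One of the 5, the stromal list, rests on 3 tested genes. The smallest adjusted exact permutation p of a list score was 0.76. The immediate early and dissociation list had an adjusted p of 0.76, with scores from 6.72 to 8.16 in CK1i and from 7.01 to 7.78 in CTRL, a median of -0.045 and a mean of 0.013. Without CK1i replicate 1 this list (median -0.56) and the chemokine list (-0.25) were called lower. The immediate early median turned to 0.22 without CK1i replicate 2, 0.12 without CK1i replicate 3 and 0.16 without CTRL replicate 1.

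The BCL2 family, p53 target, unfolded protein and type I interferon lists were not called. In the BCL2 family 11 of 13 members had lower values (camera adjusted p = 0.18), and Bcl2l11 was the 1 member that passed adjusted over the list alone (edgeR adjusted p = 0.041). Bbc3, which encodes the pro-apoptotic protein PUMA, had a log2 fold change of -0.39 ± 0.20 (SE). Among p53 targets 16 of 21 were lower (camera adjusted p = 0.090), led by Zmat3 with -0.48 ± 0.16. The unfolded protein and integrated stress list had 15 of 24 lower (camera adjusted p = 0.18). The type I interferon list had 16 of 27 higher (0.36). Calls appeared with 1 library left out: p53 targets lower without CK1i replicate 3 (median -0.25) and CTRL replicate 3 (-0.17), the integrated stress list lower without CK1i replicate 1 (-0.16), and type I interferon higher without CK1i replicate 1 (0.24) and CK1i replicate 2 (0.17). The type I interferon median turned to -0.095 without CK1i replicate 3, and without CK1i replicate 2 the p53 target median was -0.039.

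Metabolic and housekeeping groups did not pass. Cholesterol synthesis had 15 of 20 members lower (camera adjusted p = 0.070), with Hmgcs1 at a log2 fold change of -0.44 ± 0.20 (SE), and histones had 12 of 19 higher (0.070). Glycolysis and hypoxia genes had 10 higher and 10 lower (camera adjusted p = 0.99; median -0.0015, mean 0.0096), among them Pfkp, a phosphofructokinase, with -0.50 ± 0.15. Camera adjusted p was 0.099 for nuclear oxidative phosphorylation, 0.50 for mitochondrially encoded genes, 0.36 for cytosolic ribosomal proteins and 0.99 for the proteasome (median -0.0040, mean 0.0078). Cholesterol synthesis was called lower without CK1i replicate 1 (median -0.23), CK1i replicate 3 (-0.20), CTRL replicate 2 (-0.27) or CTRL replicate 3 (-0.17). Its median was -0.040 without CTRL replicate 1. Histones were called higher without CK1i replicate 3 (0.40), CTRL replicate 1 (0.42) or CTRL replicate 3 (0.50), while their median was -0.068 without CK1i replicate 2 and 0.031 without CTRL replicate 2. Oxidative phosphorylation was called higher without CK1i replicate 2 (0.10) or CTRL replicate 2 (0.12), and its median was 0.017 without CTRL replicate 1. Mitochondrial genes took 9.54% ± 1.94 of counts in CK1i and 10.0% ± 1.41 in CTRL, immunoglobulin genes 3.66% ± 0.87 and 4.20% ± 0.79, and ribosomal protein genes 2.90% ± 0.14 and 2.73% ± 0.35 (SD, n = 3). Histone genes took 0.0468% ± 0.0121 and 0.0427% ± 0.0150, haemoglobin genes 0.00054% ± 0.00016 and 0.00054% ± 0.00018, and the 10 most abundant genes 14.5% ± 1.80 and 15.4% ± 0.71. All 6 shares overlapped between the groups (exact permutation p of at least 0.5, adjusted p of at least 0.84).

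The neutrophil list had 0 to 14 counts per library and the platelet list 4 to 12, and neither had a tested gene. The T-cell list had 513 to 886 counts per library and 3 tested members (median -0.048, mean 0.15), of which Cd2 gave 198 ± 32.9 CPM in CK1i and 225 ± 59.0 CPM in CTRL (SD, n = 3). Another of the 3 was Tcf7, also in the canonical Wnt list, with a log2 fold change of 0.67 ± 0.26 (SE). Dendritic cell genes had 4 tested members, NK genes 1, erythroid genes 2 and stromal genes 3, too few for a list test. The 3 stromal genes, Col1a1 among them with 2.66 ± 0.53 and 4.59 ± 0.65 CPM, had lower values in CK1i, and their scores did not overlap (exact permutation p = 0.1). Of the erythroid genes, Tfrc, the transferrin receptor that dividing cells also use, passed adjusted over the list alone (log2 fold change -0.38 ± 0.15, SE; edgeR adjusted p = 0.046). Monocyte and macrophage genes had 1656 to 3322 counts per library and 8 tested members (camera adjusted p = 0.74; median 0.065, mean -0.049). Lyz2, C1qa, C1qb and C1qc together had at most 2.25 CPM in a library, so most of these counts came from other members. In every list other than proliferation, interferon gamma, BCL2 family and erythroid, 0 members passed adjusted over the list alone. Of the sex-linked genes, Xist was tested, at 994 to 1564 CPM in every library, and the Y-linked genes had 0 or 1 count each.

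The same heavy chain and kappa variable genes led the counts in all 6 libraries. Ighv11-2 was the leading heavy chain variable gene in each library, with 87.5% to 96.3% of 16 to 41 heavy variable counts. The exact binomial 95% intervals of these shares reached from 61.7% to 99.9%. Igkv8-28 led the kappa variable genes in every library, with 27.7% to 43.9% of counts. Of lambda variable counts, Iglv1 took most in 5 libraries and Iglv3 in CK1i replicate 2, with 8 of 15 counts. These 3' end libraries held few variable gene counts, while the constant gene Ighm had 32169 to 41971 counts per library. Kappa variable counts were spread over 8 to 13 genes in each library. The counts therefore do not settle which variable genes the leukaemia uses, or whether the libraries share a clone.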

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

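The unadjusted count, the separate S phase and G2 and M phase lists, the trend removal and the immediate early covariate were chosen after the data were seen. No gene was called with DESeq2 size factors, upper-quartile factors, library sizes without 3 gene classes, the stricter filter, limma-voom with or without weights, the legacy form, an adjusted p under 0.1, a minimum fold of 1.2 or the immediate early covariate. With no filter 2 genes were called higher and 1 lower, and with DESeq2 6 higher and 2 lower. An unadjusted p under 0.05 gave 272 and 201. Leaving out 1 library gave 0 to 1 higher and 0 to 1 lower: Traf3 without CK1i replicate 2, mt-Tq without CTRL replicate 1 and Wnt10a without CTRL replicate 3. The cause of these calls was not tested. Signs differed in 13 of 1399 combinations of named gene and setting, in 8 genes, and directions in 29 of 350 combinations of list and setting, in 16 lists that include none of the 5 called.

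Camera with an estimated correlation called 0 lists higher and 0 lower, as did fry, against 3 and 2. So the proliferation (median 0.62), heat shock (0.43), interferon gamma (0.12), circadian clock (-0.36) and MYC target (-0.13) lists lost their calls under both tests, which allow for correlated genes and leave the medians as they are by construction. Leaving out 1 library gave 3 to 6 lists higher and 0 to 8 lower. The medians then ran from 0.40 to 0.86 for proliferation, which stayed called, from 0.084 to 0.67 for heat shock, from 0.026 to 0.20 for interferon gamma, from -0.48 to -0.27 for the circadian clock and from -0.25 to -0.060 for MYC targets. Over the 12 other settings run for these lists adjusted p ran from 3.8e-43 to 0.56 for proliferation, 4.9e-16 to 0.83 for heat shock, 0.00086 to 0.68 for interferon gamma, 0.00052 to 0.56 for the circadian clock and 0.00013 to 0.76 for MYC targets. With immunoglobulin counts left out of the totals, the group differences of the ribosomal protein, mitochondrial, histone and haemoglobin shares moved by less than 1 SD. At this depth and spread, simulated 1.5-fold changes were recovered for 20.3% of genes, so changes of that size in single genes would mostly be missed.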

Other observations

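The S phase and G2 and M phase lists, the thinning, the trend removal, the immediate early covariate, the estimated correlation for the split with the most genes, and the tests of other lineages, of other B cells, of the heat shock scores and of Arntl, were chosen after the results they concern were seen. By phase of the cell cycle, 41 of 42 tested S phase genes and 46 of 48 tested G2 and M phase genes had higher values in CK1i libraries, with median log2 fold changes of 0.36 and 0.68. Camera with an estimated correlation gave p = 0.12 for S phase and p = 0.028 for G2 and M phase (adjusted over both, 0.12 and 0.056). Of these genes, 10 and 15 are also members of the proliferation list, so the lists are not independent of it. The G2 and M score minus the S score was 0.35 ± 0.10 in CK1i and 0.07 ± 0.03 in CTRL (SD, n = 3), without overlap of the groups (exact permutation p = 0.1, the smallest possible).

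Per1 varied within both groups. It was at 117, 114 and 119 CPM in CK1i replicate 1, CTRL replicate 1 and CTRL replicate 3, and at 30.99, 33.7 and 45.1 CPM in CK1i replicate 2, CK1i replicate 3 and CTRL replicate 2. Of the 10 splits of the libraries into 3 and 3, the one that sets those 3 libraries against the other 3 called the most genes, 18, all of them higher, where the comparison by treatment called 0. Of the 18, Klf4 and Klf6 are the 2 members of the immediate early list. The others include Per1, Rhob, H1f2, Mt1, Tsc22d3, Klf2 and Trp53inp2. Nr4a1, Rel, Nfkbid and Cd69, also among them, are members of the B-cell activation list. The immediate early score was 8.16, 7.78 and 7.43 in CK1i replicate 1, CTRL replicate 1 and CTRL replicate 3. In CK1i replicate 2, CK1i replicate 3 and CTRL replicate 2 it was 6.72, 6.88 and 7.01. Because the split was singled out for its count, that count alone does not establish a structure of the samples. The genes and lists of this split are descriptions of these libraries. Camera with the preset correlation called 12 lists in that split, among them the immediate early, circadian clock and heat shock lists as higher and the proliferation list as lower. With an estimated correlation it called 0 (immediate early list p = 0.013, adjusted p = 0.25).

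The 6 libraries make 10 splits into 3 and 3, the real 1 included, too few for a share under 0.05. The real split gave 0 genes and the highest other 18. By camera with the preset correlation it gave 5 lists, the fewest of the 10 splits, where the others gave 6 to 12. The number of called lists therefore does not set the comparison by treatment apart. The median of the proliferation list was 0.62 in the real split and at most 0.53 in size in any other.

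For the higher proliferation list, the median was 0.59 after thinning all libraries to the smallest total, against 0.62 in the main fit. After removing trends on GC content and length it was 0.65. Both stayed above 0.3, which argues against either as the whole cause. No SE of these medians was computed. The SE of the difference in list scores was 0.28, and against it the margin after thinning was narrow. Both corrections were mild: library totals already overlapped between the groups, and the trend removal moved genes by a median of 0.021. With the immediate early score as a covariate the median was 0.58 (SE of the score difference 0.26), a similarly narrow margin. The immediate early score itself overlapped between the groups, at 7.25 ± 0.79 in CK1i and 7.40 ± 0.39 in CTRL (SD, n = 3). The covariate could therefore hardly move the median, and early stress stays open. Abundant erythroid, T-cell, neutrophil and macrophage transcripts reached at most 19.01 CPM in a CK1i library. The list's sum differed by 1397 CPM, which argues against cycling cells of those lineages. A lead from 1 library stays open. The lowest median with a library left out, 0.40 without CTRL replicate 1, exceeded 0.3 by less than 0.28, the SE of the score difference. Cycling non-leukaemic B cells also stay open, although the cells were sorted as leukaemic. The follicular and marginal zone score was 6.14 ± 0.05 in CK1i and 5.95 ± 0.15 in CTRL (SD, n = 3). The share of Ighv11-2 was 72 of 78 counts in CK1i and 80 of 86 in CTRL (Fisher's exact p = 1.0), too few to find a small admixture. An effect of treatment on cycling of the leukaemia cells is a further open explanation that these data do not test.

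The heat shock list may reflect stress that varied between libraries of both groups. The difference of group means was 0.89 times the mean SD within groups, below a bound of 1 SD set after the scores were seen. With so few libraries, a difference of this size can arise with or without an effect of treatment, so it does not decide the cause. With the immediate early score as a covariate the median was 0.55 (SE of the score difference 0.35), against 0.43 without it. This cannot decide about stress that follows that score. The error was wide, and the immediate early score was slightly lower in CK1i than in CTRL (7.25 against 7.40). An effect of treatment stays open as untested.

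The lower circadian clock list was weighed against the hour of sampling and against early stress. Arntl, which cycles opposite to the Per genes, had a log2 fold change of 0.045 ± 0.16 (SE), between the outcomes that a shifted hour and a joint fall would give, so a shifted hour stays open. With the immediate early score as a covariate the median was -0.35, against -0.36 without it. It was beyond the bound of -0.2 by more than 0.11, the SE of the score difference. The immediate early score overlapped between the groups, so the covariate could hardly move the median. The score did follow the split with the most genes, at 7.43 to 8.16 on its higher side and 6.72 to 7.01 on the other. Per1, a clock gene, was called higher on that side, as was the circadian clock list by camera with the preset correlation. Early stress and variation between libraries along that split therefore stay open. Inhibition of the casein kinases, which act on the PER proteins, stays open as untested.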
